A study of Mus musculus with 14 samples.

How the data were processed

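RNA was measured by sequencing in 14 libraries of cells sorted by fluorescence-activated cell sorting (FACS) from mouse dermis, taken from the wound bed on day 5 after injury in male C57/BL6 mice aged 7 weeks, per the labels. The labels gave 7 groups of 2 libraries each. The newly deposited set held 6 libraries in 3 groups, named here Adipocyte, AdipoqTraced and CD26 as in the sample titles. The other set held 8 libraries in 4 groups that the labels mark as a renewed analysis of an earlier series, named here AP_CD9Low, AP_CD9High, CD29 and DN. CD26 is the protein made from Dpp4, CD29 the protein made from Itgb1, and CD9 the protein made from Cd9. The labels do not spell out AP and DN, and per the file headers the CD29 libraries were CD29-high and the DN libraries CD29-low. The gates used for sorting are not given in the sources used here. No group was present in both sets, so the set and the group cannot be told apart in any comparison between them. The labels do not say that the 2 replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

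Per the labels' protocols, RNA was extracted with a kit for very small cell numbers and complementary DNA was made with the SMARTer Ultra Low RNA kit before Illumina libraries were prepared. The submitters' processing notes name CASAVA 1.8.2, HISAT2 2.1, StringTie 1.3.3b, DESeq2 without a version, and the mouse genome build mm10, with no role or order. The annotation release, the strand setting and the read filters are not given in the sources used here. The deposited table held whole-number read counts per gene, one column per library, with Ensembl gene identifiers and no normalisation. On inspection the values were whole numbers, with library totals of 13760557 to 22218364. All 52636 genes of the table entered the work, 0 columns belonged to other samples, and 23877 genes were at 0 in every library. Symbols and coordinates were taken from the mouse GENCODE release M21 annotation of mm10, in which 52403 identifiers matched once version numbers were ignored and 49035 with them. The 233 identifiers without a symbol held at most 0.052% of the counts of any library, and 147 genes shared a symbol with another. The counting was treated as unaware of strand, so overlapping genes and near-identical copies are reported as uncertain.

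The main test was the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust = TRUE and glmQLFTest, two-sided) in R 4.3.3, on counts scaled by the trimmed mean of M values (TMM). Genes were kept by filterByExpr with the group as factor, which left 18394. One coefficient was fitted per group across all 14 libraries, which left 7 residual degrees of freedom, with a prior of 9.7. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. In 8 comparisons, the first group named was set against the second, so that a positive log2 fold change means higher in the first. AP stands for the mean of the AP_CD9Low and AP_CD9High coefficients with a weight of 0.5 each. Libraries of AP_CD9Low and AP_CD9High carry the same label numbers, 2 and 4, so n = 4 for AP counts libraries that may not be separate samples. Levels are CPM from the cpm function of edgeR after TMM scaling, as mean ± SD over the libraries of a group. SE is an approximate standard error, the absolute log2 fold change divided by the square root of its F statistic. Where every library of a group was at 0, the fold is a lower bound against a floor of 3 counts over that group. Such floors cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

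Before the data were examined, 27 gene lists, the comparisons, the tests and the rule for naming genes were fixed. The lists covered lipid metabolism, extracellular matrix, contraction, signalling, cell cycle and the markers of other skin cell types, and 647 of their 661 entries matched the table. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and a list with fewer than 5 tested members would have been left out. Beside it stand camera with a correlation estimated per list, the directional test of fry, which asks whether a list's genes move one way on balance without comparing them with other genes, and the members called when p-values were adjusted over the list alone. The rule named the genes of the labels and usual sorting markers (Adipoq, Dpp4, Cd9, Itgb1, Cd34, Ly6a and Pdgfra), the 5 largest rises and 5 largest falls with at least 10 CPM in a group and no overlap between libraries, and the 2 called members with the smallest p from each list with at least 3. Not every gene so named is printed. One of them is not reported here. Acta2 and Col1a1 in the comparison with adipocytes, and Tpsb2, Cma1, mt-Cytb and mt-Nd6 in that of CD29 with DN, were chosen after their values were seen.

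The test was also run on simulated counts for the same 18394 genes, drawn from the fitted means, spreads and library sizes with 200 genes changed per comparison. There it was too liberal: 87 of 342 calls over the 8 comparisons (25.4%) were false where the threshold allows 5%, with 15.2% to 32.9% per comparison. The same fit with legacy = TRUE, the older way in which edgeR estimates the quasi-likelihood spread, gave 22 false calls of 239 (9.2%). DESeq2, run on simulated counts for 2 comparisons, gave 37 false calls of 72 (51.4%) in AdipoqTraced against Adipocyte and 49 of 95 (51.6%) in AP_CD9High against AP_CD9Low. These shares belong to simulations with 200 changed genes and need not hold where more genes differ. Each gene was also drawn with the same spread in every library, whereas real replicates were less alike in the new set than in the reanalysed set. The shares of false calls and of recovered genes need not hold under such unequal spread. The main test was kept as fixed, and the counts with legacy = TRUE are given where they differ by over 1.5 times. For AdipoqTraced against Adipocyte, 7.5% of genes changed 4-fold and 18.2% of those changed 8-fold were recovered in the simulation, so genes not called may still differ. In each of the 8 simulated comparisons the list raised on purpose was called and 0 of 20 unchanged lists were. The simulated counts were drawn with no correlation between the genes of a list built in. The list result therefore cannot tell whether the preset correlation of camera was high enough for the real lists.

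Alternatives covered the scaling (relative log expression, or library size alone), the filter on low counts, the test (DESeq2 1.42.0, glmQLFit without robust, glmTreat against a fold of 1.5), the libraries in the fit, each library left out in turn, the replicate number as a block, and genes with the same symbol summed. Genes of the mitochondrial genome left out, legacy = TRUE, and lists tested within one set were added after the data were seen. Other values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. With 2 libraries per group, no count of other splits of the samples was made.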

Results

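Gene expression was measured in 14 libraries of cells sorted from the dermal wound bed of mice on day 5 after injury, with 2 libraries in each of 7 groups. The newly deposited set held mature fat cells (Adipocyte), cells labelled as traced by Adipoq (AdipoqTraced, described as GFP in the labels) and CD26 cells. The other set held AP_CD9Low, AP_CD9High, CD29 and DN cells. The title of the series concerns adipocytes and cells derived from them after skin injury. The comparisons asked how AdipoqTraced cells differed from adipocytes and from CD26 cells, and how the populations of the other set differed from one another.

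Total counts lay between 13760557 and 22218364 per library. Genes of the mitochondrial genome took 79.07% and 84.79% of the counts in the Adipocyte libraries, 18.45% and 26.74% in AdipoqTraced, 35.45% and 38.77% in CD26, and 0.19% to 0.94% in the other set. This left 2952186 and 3255546 counts outside the mitochondrial genome in the Adipocyte libraries, against 10081318 to 22133663 in the other 12. A count of 0 in both Adipocyte libraries therefore sets a less strict bound. TMM factors were 0.302 and 0.239 in Adipocyte and between 0.837 and 1.598 elsewhere. With library size alone as the scaling, the median log2 fold change of all genes moved from 0.19 to 2.25 in AdipoqTraced against Adipocyte and from 0.24 to 1.95 in CD26 against Adipocyte. It moved from 0 to 0.27 in AdipoqTraced against CD26, from 0.1 to 0.39 in CD29 against AP, from 0 to 0.21 in DN against AP and from 0.14 to 0 in AdipoqTraced against AP.

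**Figure D1:**
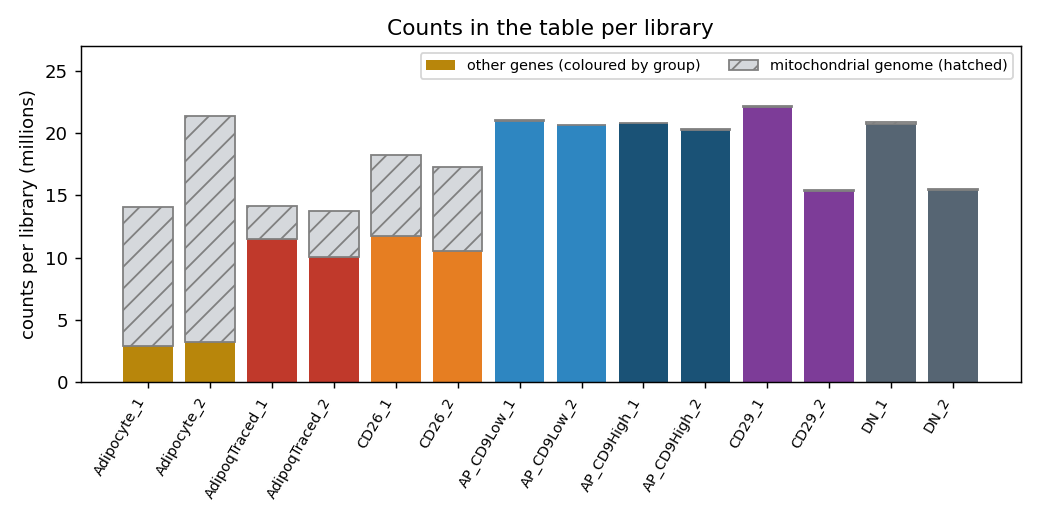
Total counts for each of the 14 libraries, as bars coloured by group, with the part on the mitochondrial genome hatched in grey. That part reached 79.07% and 84.79% in the Adipocyte libraries and stayed at or under 0.94% in the 8 libraries of the AP, CD29 and DN groups.

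Libraries of a group were more alike in the reanalysed set (Pearson r across the tested genes of 0.907 to 0.934 on log2 CPM) than in the new set (0.827 for Adipocyte, 0.811 for AdipoqTraced and 0.863 for CD26). The AdipoqTraced libraries correlated with the CD26 libraries at 0.784 to 0.833, about as well as with one another. Correlations across genes describe these libraries, and genes are not independent replicates. No pair of replicates held identical values, and all 7 pairs differed by far more than counting noise (chi-square per degree of freedom of 47.45 to 108.6). On the first 2 dimensions of multidimensional scaling, the 8 libraries of the reanalysed set lay together, AdipoqTraced lay next to CD26, and Adipocyte stood apart from both.

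**Figure D2:**
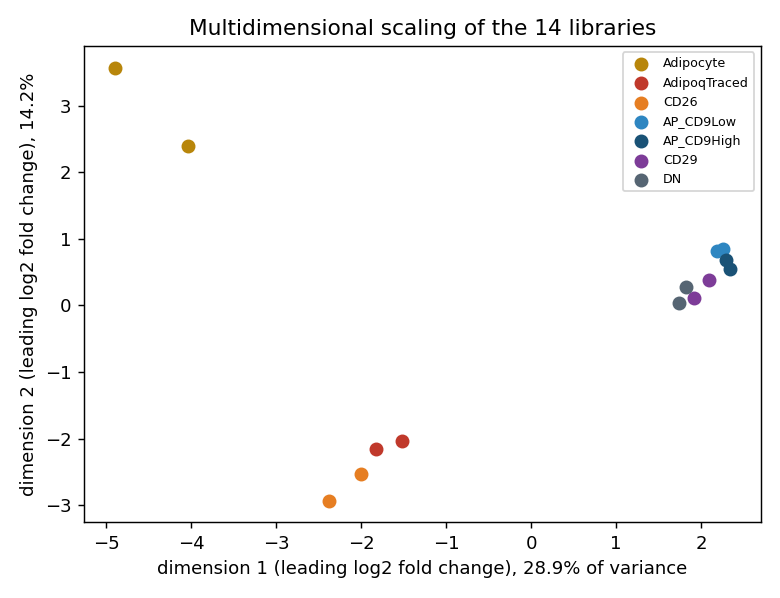
Multidimensional scaling of the 14 libraries, with the first dimension (28.9% of variance) and the second (14.2%) as leading log2 fold changes and each point a library coloured by group. The Adipocyte libraries lie at -4.9 and -4.04 on the first dimension, AdipoqTraced and CD26 between -2.38 and -1.52, and the reanalysed set between 1.74 and 2.34.

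AdipoqTraced cells lacked most of the fat cell programme at the level seen in adipocytes and carried that of matrix-producing cells. Adipoq (chromosome 16, 23146536 to 23158028, mm10), which encodes adiponectin, was at 855.2 ± 225.7 CPM in Adipocyte and 8.95 ± 9.02 CPM in AdipoqTraced (log2 fold change -6.58, SE 0.81, adjusted p = 0.000141, n = 2 per group). The AdipoqTraced libraries held 15.33 and 2.57 CPM of Adipoq, and its log2 fold change ran from -8.37 to -4.56 over 18 alternatives. Leptin (Lep) was at 160.4 ± 68.76 CPM in Adipocyte and at 0 counts in both AdipoqTraced libraries, at least 1620-fold lower. In the other direction, the fibril-associated collagen Col12a1 (chromosome 9, 79598991 to 79718831) was at 3667 ± 104.0 against 26.36 ± 6.387 CPM (7.11, SE 0.28, adjusted p = 2.02e-10) and tenascin C (Tnc) at 3039 ± 194.6 against 30.09 ± 3.036 CPM (6.65, SE 0.33). In all, 1921 genes were called in AdipoqTraced against Adipocyte, 1032 higher and 889 lower.

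All 26 tested adipocyte identity genes fell (median log2 fold change -7.46, list adjusted p = 2.47e-25; 26 lower adjusted over the list alone). The lipid droplet protein gene Cidec fell by 8.98 (SE 0.6) and the triglyceride lipase gene Pnpla2 by 6.09 (SE 0.34) on the log2 scale. Of 23 genes of fatty acid and triglyceride synthesis, 20 fell (adjusted p = 4.2e-23; 22 adjusted over the list alone). The desaturase gene Scd1 was at 35.28 ± 20.52 against 24360 ± 9514 CPM and fatty acid synthase (Fasn) at 48.95 ± 25.49 against 5096 ± 1175 CPM. Lipolysis and lipid droplet genes fell in 13 of 20 cases (adjusted p = 2.8e-11; 14 adjusted over the list alone). Fatty acid oxidation genes fell in 14 of 23 (adjusted p = 4.58e-14; 16 lower and 1 higher adjusted over the list alone). Nuclear genes of mitochondrial respiration were lower in 10 of 30 cases, with adjusted p = 3.29e-11 for the list and adjusted p = 0.0803 with an estimated correlation (16 lower adjusted over the list alone). Single genes of the list depended on the scaling. Sdha went from -2.65 (SE 0.25) to -0.62 with library size alone and lost its call (adjusted p = 0.0656, range 4.3e-28 to 0.0656 over its 18 alternatives), and the ATP synthase gene Atp5b turned from -1.35 (SE 0.19) to 0.69. The thermogenic list had 3 of 11 genes lower (adjusted p = 0.0178, and adjusted p = 0.0803 with an estimated correlation; 5 adjusted over the list alone).

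Of 34 fibrillar and interstitial matrix genes, 33 rose (median 3.23, list adjusted p = 5.64e-41; 33 adjusted over the list alone). Of 27 collagen processing and cross-linking genes, 26 rose (adjusted p = 2.47e-25; 26 adjusted over the list alone), including the lysyl hydroxylase gene Plod2 (4.68, SE 0.39) and the collagen chaperone gene Fkbp10 (5.23, SE 0.48, and 8.13 without Adipocyte replicate 2). Type I collagen (Col1a1), named after its values were seen, rose by a log2 fold change of 2.54 (SE 0.29) from an Adipocyte level that was already 2340.86 and 5320.34 CPM in the 2 libraries. Contractile and cytoskeletal genes rose in 14 of 26 cases (adjusted p = 1.14e-15; 22 adjusted over the list alone), with filamin A (Flna) at 3.78 (SE 0.25). Smooth muscle actin (Acta2, chromosome 19, 34241090 to 34255590), also named afterwards, rose by 4.76 (SE 0.34). Matrix proteases and their inhibitors rose in 19 of 28 cases with 1 lower (adjusted p = 2.51e-14; 20 higher and 1 lower adjusted over the list alone). The protease inhibitor gene Timp1 (5.68, SE 0.42) and the plasminogen activator gene Plat (5.1, SE 0.37) led them.

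Ligands, receptors and targets of TGF-beta rose in 13 of 28 cases (adjusted p = 1.95e-06; 17 adjusted over the list alone), with Inhba at 3.75 (SE 0.33) and Thbs1 at 2.04 (SE 0.25). Cell cycle genes rose in 19 of 36 cases (adjusted p = 7.69e-16; 23 adjusted over the list alone), with the proliferation marker Mki67 at 224.3 ± 23.34 against 32.27 ± 0.8653 CPM. Chemokines and cytokines were higher in 14 of 31 cases and lower in 2 (adjusted p = 3.54e-10, and adjusted p = 0.0803 with an estimated correlation; 18 higher and 3 lower adjusted over the list alone), among them the prostaglandin synthase gene Ptgs2 (3.05, SE 0.27) and Ccl2 (2.35, SE 0.25). Fibroblast progenitor markers had 5 of 27 genes higher and 2 lower (adjusted p = 0.0135, and adjusted p = 0.272 with an estimated correlation; 11 higher and 2 lower adjusted over the list alone). The platelet-derived growth factor receptor gene Pdgfra was at 285.2 ± 1.39 against 27.16 ± 36.75 CPM (3.32, SE 0.53). The Adipocyte libraries held 1.17 and 53.15 CPM of Pdgfra, and its log2 fold change was 2.49 without Adipocyte replicate 1 and 7.97 without Adipocyte replicate 2. Pdgfra was not called with legacy = TRUE (adjusted p = 0.0626, range 2.38e-07 to 0.0626 over its 18 alternatives). Cd34 (1.06, SE 0.36, adjusted p = 0.0742) and Ly6a (0.63, SE 0.42, adjusted p = 0.435) were not called. Dpp4 (0.33, SE 0.4, adjusted p = 0.714) was not called either, except in 1 of 18 alternatives (range of log2 fold change -0.19 to 2.43). Without AdipoqTraced replicate 2, Cd34 was called (adjusted p = 0.0192), and without Adipocyte replicate 2, Ly6a was called (adjusted p = 0.00482). Over 18 alternatives the adjusted p ran from 1.45e-06 to 0.478 for Cd34 and from 2.07e-05 to 1 for Ly6a, with positive log2 fold changes throughout.

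Markers of other cell types also differed between these groups. Skeletal muscle genes were lower in AdipoqTraced in 11 of 17 cases (adjusted p = 1.41e-08, and adjusted p = 0.123 with an estimated correlation; 14 adjusted over the list alone). The troponin gene Tnnt3 was at 75.43 ± 24.31 CPM in Adipocyte and 0 counts in AdipoqTraced, at least 798-fold lower. Macrophage and monocyte markers were higher in 7 of 26 cases (adjusted p = 0.00196, and adjusted p = 0.419 with an estimated correlation; 9 higher and 1 lower adjusted over the list alone). The mean log2 CPM of the list overlapped between the groups, at 6.18 and 5.5 in AdipoqTraced against 4.31 and 5.54 in Adipocyte. Cd14 was at 247.7 ± 99.4 against 35.72 ± 5.021 CPM. Keratinocyte markers had 1 of 24 genes higher (adjusted p = 0.0294, and adjusted p = 0.489 with an estimated correlation; 0 adjusted over the list alone). Of the 27 lists, 17 were called with the preset correlation and 10 with an estimated one, namely those of adipocyte identity, synthesis, lipolysis, oxidation, matrix, collagen processing, contraction, TGF-beta, proteases and cell cycle.

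The count of 1921 fell to 960 without Adipocyte replicate 1 and to 1145 with only these 4 libraries in the fit. With library size alone as the scaling, 7946 genes were higher and 249 lower. DESeq2 called 3402, but in the simulation of this comparison 51.4% of its calls were false. Adipoq lost its call with legacy = TRUE (adjusted p = 0.143) and with DESeq2, over a range of adjusted p from 2.05e-05 to 0.143 across its 18 alternatives.

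**Figure D3:**
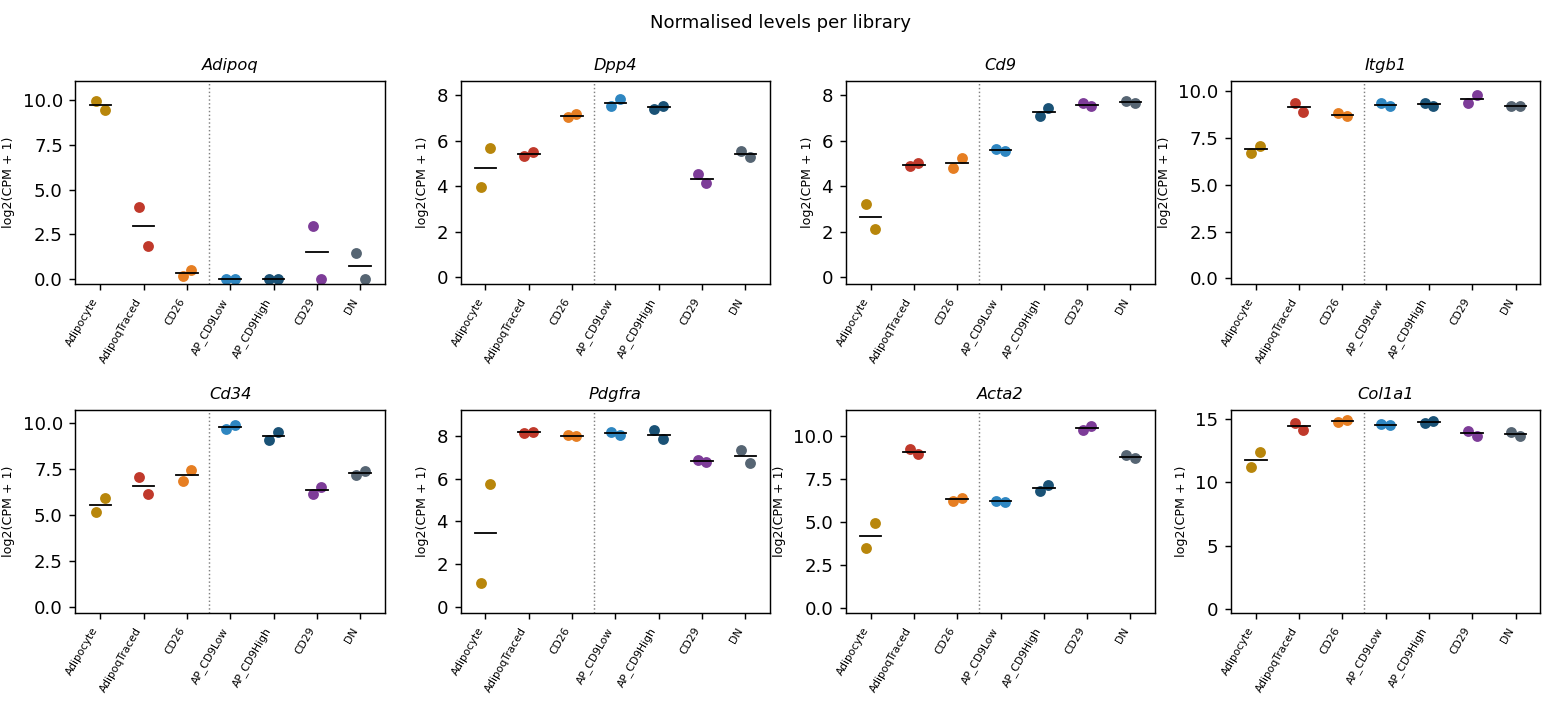
Normalised levels as log2(CPM + 1) of 8 genes in each library, with points coloured by group, horizontal lines for the mean of the 2 libraries and a dotted line between the new and the reanalysed set. Acta2 stands higher in AdipoqTraced (545.0 CPM) than in CD26 (78.12 CPM), and Adipoq was at 0 in all 4 AP libraries. Dpp4, the gene of the protein that names the CD26 group, stands lower in AdipoqTraced (41.73 against 135.5 CPM).

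Set against CD26 cells, AdipoqTraced cells had more Acta2 and Csrp1 and less Dpp4, the gene of the protein that names the CD26 group. Acta2 was at 545.0 ± 84.92 against 78.12 ± 5.653 CPM (log2 fold change 2.8, SE 0.27, adjusted p = 5.37e-05, n = 2 per group). The LIM protein gene Csrp1 was at 292.0 ± 53.31 against 64.04 ± 2.569 CPM (2.19, SE 0.25, adjusted p = 0.000257). Dpp4 (chromosome 2, 62330073 to 62412231), which encodes CD26, was at 41.73 ± 3.181 against 135.5 ± 6.948 CPM (-1.7, SE 0.34, adjusted p = 0.0109). That is the direction of the name of the CD26 group, and the call was lost in 6 of 18 alternatives. Adipoq was at 15.33 and 2.57 CPM in the AdipoqTraced libraries and 0.12 and 0.42 CPM in CD26, a difference that did not pass the test (5.09, SE 1.83, adjusted p = 0.15). In total 710 genes were called in AdipoqTraced against CD26, 436 higher and 274 lower, with the spread of each gene estimated over all 14 libraries.

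Of 26 contractile genes, 10 rose and 0 fell (median 0.95, list adjusted p = 3.84e-08, and adjusted p = 0.111 with an estimated correlation; 13 higher and 1 lower adjusted over the list alone). Caldesmon (Cald1) went the other way without being called (-0.77, SE 0.21, adjusted p = 0.0517). Pericyte and smooth muscle markers were higher in 3 of 16 cases (adjusted p = 0.00416, and adjusted p = 0.13 with an estimated correlation; 4 higher and 1 lower adjusted over the list alone). Mcam was at 92.85 ± 46.84 against 13.58 ± 2.126 CPM and Cspg4 at 40.55 ± 18.7 against 4.713 ± 0.01275 CPM. Mitochondrial respiration genes were higher in 6 of 30 cases and lower in 1 (adjusted p = 4.34e-07, and adjusted p = 0.473 with an estimated correlation; 12 higher and 1 lower adjusted over the list alone), including the cytochrome oxidase subunit genes Cox4i1 (1.79, SE 0.31) and Cox6a1 (1.79, SE 0.33, and 1.11 without AdipoqTraced replicate 1). The make-up of the RNA differed between these groups as well. Nuclear ribosomal RNA genes, with the overlapping AY036118 and Gm26917, took 7.99% and 3.127% of the counts in AdipoqTraced against 1.582% and 1.359% in CD26, and mitochondrial ribosomal RNA 17.52% and 25.14% against 33.22% and 36.28%. Cell cycle genes were higher in 4 of 36, and in 5 adjusted over the list alone (list adjusted p = 0.00174, and adjusted p = 0.326 with an estimated correlation). Among them was the cyclin gene Ccnb2 (2.09, SE 0.43), which lost its call in 8 of 18 alternatives (log2 fold change 1.48 to 2.49). Chemokines and cytokines were lower in 5 of 31 (adjusted p = 0.00174, and adjusted p = 0.616 with an estimated correlation; 8 adjusted over the list alone). The neutrophil attractant gene Cxcl3 was at -2.0 (SE 0.3) and Ptgs2 at -1.02 (SE 0.23). Cxcl3 lost its call in 2 of 18 alternatives and Ptgs2 in 8 of 18.

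The matrix list was not called (adjusted p = 0.184), with 5 genes higher and 2 lower, or 9 and 3 adjusted over the list alone. Type VI collagen genes rose, Col6a3 by 1.72 (SE 0.2) and Col6a1 by 1.2 (SE 0.19). The basement membrane list was not called either (adjusted p = 0.228), with 2 genes higher and 1 lower, or 6 and 4 adjusted over the list alone. Its collagens Col15a1 (2.26, SE 0.39) and Col18a1 (2.01, SE 0.41) were called, but Col15a1 not without CD26 replicate 1 or 2 (range of adjusted p 0.000348 to 0.0816), and Col18a1 not in 5 of 18 alternatives (range 0.000252 to 0.174), among them those without AdipoqTraced replicate 1 and without CD26 replicate 1 or 2. Collagen processing genes were higher in 4 of 27 cases and lower in 2 (adjusted p = 0.0445, and adjusted p = 0.733 with an estimated correlation; 7 higher and 3 lower adjusted over the list alone). Pcolce was at 1.31 (SE 0.23). Thy1, a surface marker of fibroblasts, was at 324.0 ± 39.83 against 80.59 ± 1.871 CPM (2.01, SE 0.34). Inhba was lower (-1.31, SE 0.27), as was the angiogenic factor gene Vegfa (-1.12, SE 0.25). Adipocyte identity genes had 2 of 26 higher (adjusted p = 0.205; 3 higher and 1 lower adjusted over the list alone). Pdgfra (0.16, SE 0.42), Cd34 (-0.51, SE 0.31), Ly6a (-0.25, SE 0.4), Cd9 (-0.1, SE 0.3) and Itgb1 (0.39, SE 0.23) were not called. Among the largest differences, the anion transporter gene Slc26a7 was at 33.21 ± 16.03 CPM in CD26 and 0 counts in AdipoqTraced, at least 336-fold lower. Mup17, at 25.41 ± 5.794 CPM in AdipoqTraced and 0 counts in CD26, belongs to a family of near-identical genes, and Rbm12 (33.44 ± 17.38 CPM against 0 counts) overlaps Cpne1, so both are uncertain.

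The count of calls moved with the libraries in the fit, and leaving 1 out leaves a lone library in its group. The 710 calls became 203 without AdipoqTraced replicate 1, 878 without AdipoqTraced replicate 2, 184 without CD26 replicate 1 and 69 without CD26 replicate 2. Of 26 called genes followed through the alternatives 13, 19 and 21 lost the call in the 3 fits with fewer calls. For Dpp4 the log2 fold change in these 3 was -1.65, -1.77 and -1.69, close to its -1.7, while the adjusted p was 0.0878, 0.0549 and 0.0944 (range 0.00135 to 0.118 over its 18 alternatives). Acta2, Csrp1 and Col6a3 were called in all 18. Calls were also lost in the fit with more calls, without AdipoqTraced replicate 2. With only these 4 libraries in the fit, 17 of the 26 called genes followed lost theirs. The count was 342 with legacy = TRUE, 422 without a filter on low counts, 202 against a fold of 1.5 and 1251 in DESeq2. It was 75 with the new set alone and 92 with only these 4 libraries. In those fits the spread of a gene came from the new set, whose replicates were less alike than those of the reanalysed set. The 710 calls therefore rest on a spread shared with the other set. Whether the unequal spread accounts for the drop was not tested. With library size alone as the scaling the split was 1026 higher and 140 lower.

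**Figure D4:**
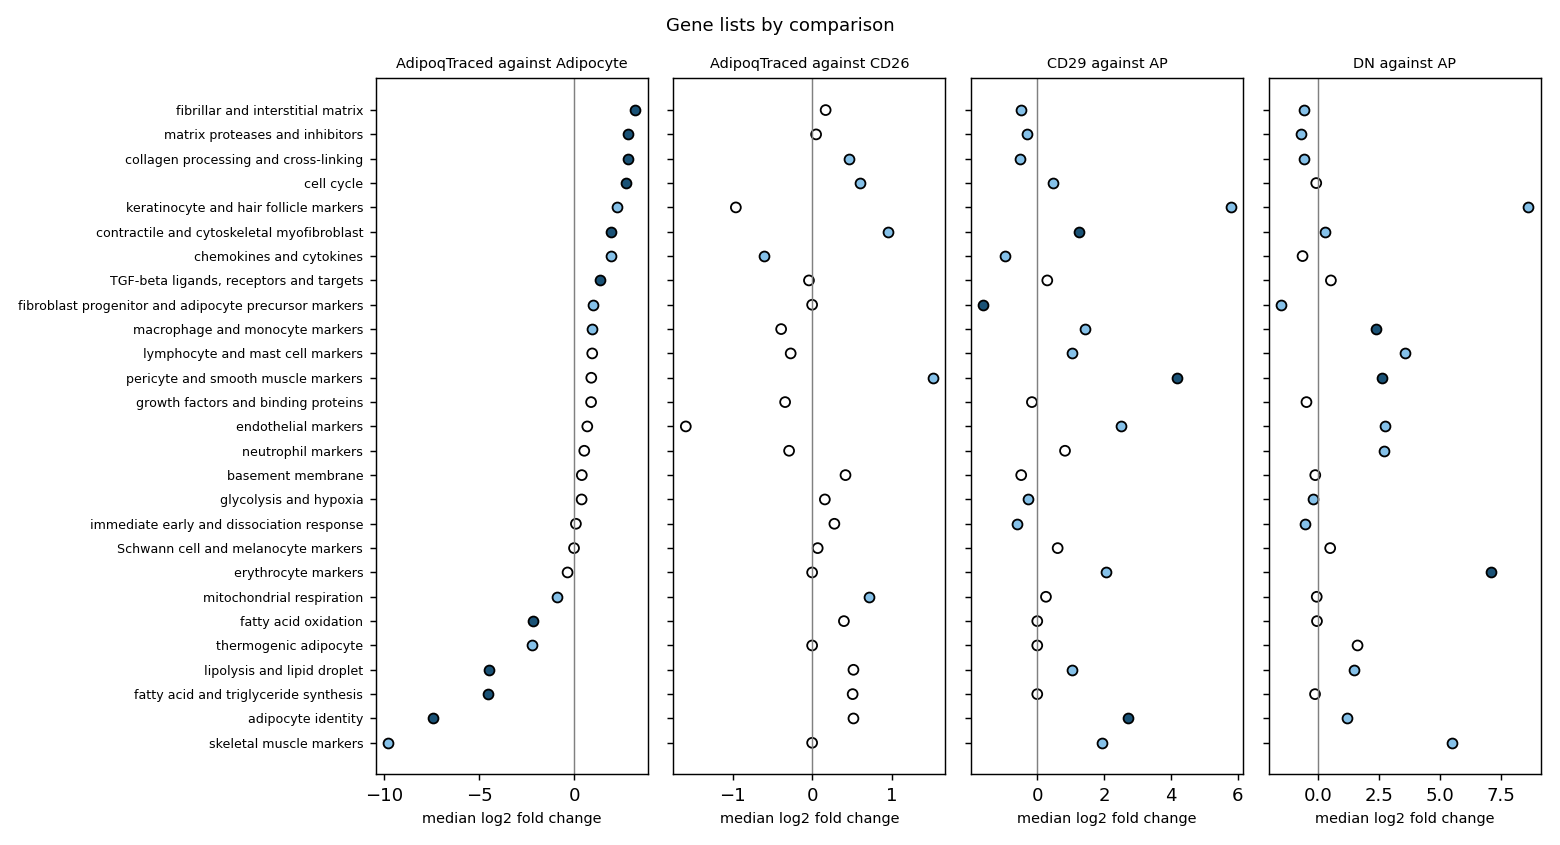
Median log2 fold change (horizontal axis) of each of the 27 gene lists in 4 comparisons. Open points mark lists not called by camera, light blue points lists called with the preset correlation only, and dark blue points lists called also with an estimated correlation: 10 lists in AdipoqTraced against Adipocyte, 0 in AdipoqTraced against CD26, 4 in CD29 against AP and 3 in DN against AP.

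CD26 cells had less of the lipid and more of the matrix transcripts than adipocytes, in a comparison that shares its Adipocyte libraries with that of AdipoqTraced. Adipoq was at 0.2673 ± 0.209 against 855.2 ± 225.7 CPM (log2 fold change -11.67, SE 1.22, adjusted p = 3.56e-05, n = 2 per group), and resistin (Retn) at 0 counts against 163.5 ± 19.98 CPM, at least 1710-fold lower. Dpp4 was higher in CD26 (2.03, SE 0.39, adjusted p = 0.00171, and 3.31 without Adipocyte replicate 2), the direction of the group name. Also higher were Pdgfra (3.16, SE 0.53, and 7.85 without Adipocyte replicate 2), Cd34 (1.57, SE 0.36), Cd9 (2.52, SE 0.49) and Itgb1 (1.85, SE 0.25). Without Adipocyte replicate 1, Cd34 was not called (adjusted p = 0.103), nor was it without CD26 replicate 2 (adjusted p = 0.0781), and Cd9 was not called without Adipocyte replicate 2 (adjusted p = 0.0606). The calls of Adipoq (range of adjusted p 5.93e-07 to 0.0596) and Pdgfra (8.67e-07 to 0.0835) ended with legacy = TRUE, at adjusted p = 0.0596 and 0.0737. Of 1956 genes called, 1002 were higher and 954 lower.

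All 26 adipocyte identity genes and all 23 synthesis genes fell (list adjusted p = 2.35e-27 and 4.06e-27; 26 and 23 adjusted over the list alone). Respiration genes fell in 23 of 30 cases (adjusted p = 1.85e-23; 27 adjusted over the list alone), among them the citrate synthase gene Cs (-2.52, SE 0.29). Of 34 matrix genes 30 rose (adjusted p = 1.23e-37; 31 adjusted over the list alone), with Col12a1 at 6.52 (SE 0.28). Of 31 chemokines and cytokines, 19 rose and 2 fell (adjusted p = 1.26e-14; 21 and 3 adjusted over the list alone), with Ptgs2 at 4.08 (SE 0.28). Macrophage and monocyte markers were also higher, in 7 of 26 and in 14 adjusted over the list alone. Their list had adjusted p = 1.5e-05, and adjusted p = 0.25 with an estimated correlation. Their counts came to 0.617% and 0.439% of the TMM-scaled library size in CD26, against 0.154% and 0.319% in Adipocyte. Endothelial markers were higher in 2 of 21 (adjusted p = 0.0117, and adjusted p = 0.175 with an estimated correlation; 0 adjusted over the list alone). The epidermal growth factor family gene Ereg was at 269.3 ± 41.29 CPM in CD26 and at 0 and 4.69 CPM in the Adipocyte libraries (6.72, SE 0.86). Its fold rests on Adipocyte replicate 2, at 5.95 without Adipocyte replicate 1. Keratinocyte markers were higher in 8 of 24 cases (adjusted p = 0.00163, and adjusted p = 0.3 with an estimated correlation; 10 higher and 1 lower adjusted over the list alone). Krt1 was at 388.4 ± 302.2 against 6.587 ± 5.33 CPM. Skeletal muscle genes were lower in 12 of 17 (adjusted p = 6.51e-09, and adjusted p = 0.115 with an estimated correlation; 15 adjusted over the list alone). The count fell to 964 without Adipocyte replicate 1 and to 1225 without CD26 replicate 2, and with library size alone as the scaling 6203 genes were higher and 298 lower. Of the lists, 19 were called with the preset and 12 with an estimated correlation.

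Between AP_CD9High and AP_CD9Low cells, 4 genes were called, 3 higher and 1 lower, against 673 at an unadjusted p under 0.05 in edgeR. In the simulation of this comparison the test recovered 0% of genes changed 2-fold, 17.9% of those changed 4-fold and 25.8% of those changed 8-fold, so genes not called may still differ. Cd9 itself (chromosome 6, 125460266 to 125494791) was at 153.7 ± 28.24 in AP_CD9High against 46.78 ± 1.87 CPM in AP_CD9Low (log2 fold change 1.72, SE 0.27, adjusted p = 0.0317, n = 2 per group), the direction of the sort. The cartilage matrix gene Cilp was at 163.6 ± 33.6 against 20.55 ± 14.93 CPM (2.99, SE 0.44, adjusted p = 0.0198). The small GTPase gene Rac1 (chromosome 5, 143503634 to 143528036) was at 391.4 ± 19.3 against 112.6 ± 13.24 CPM (1.8, SE 0.2, adjusted p = 0.00205). Pcdhgc4 was at 1.57 and 0 CPM in the AP_CD9High libraries against 36.94 ± 17.62 CPM (-5.55, SE 0.76, adjusted p = 0.0042, and -4.54 without AP_CD9High replicate 2, the one at 0), and is uncertain because the genes of its cluster share exons.

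Dpp4 (-0.21, SE 0.31), Cd34 (-0.46, SE 0.3), Ly6a (-0.35, SE 0.39), Pdgfra (-0.05, SE 0.42) and Itgb1 (0.0, SE 0.22) were not called. Macrophage and monocyte markers had a positive log2 fold change in 24 of 26 cases (median 0.77, list adjusted p = 2.03e-09, and adjusted p = 0.49 with an estimated correlation), with 0 genes called over all genes and 8 higher adjusted over the list alone. The contractile list (median 0.35, adjusted p = 0.00187, and adjusted p = 0.49 with an estimated correlation; 0 adjusted over the list alone) passed with the preset correlation only. So did the lymphocyte and mast cell list (median 1.05, adjusted p = 0.00422, and adjusted p = 0.49 with an estimated correlation; 0 adjusted over the list alone).

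Each of the 4 calls was lost in some fits. Without AP_CD9Low replicate 2, edgeR called 0 genes, with 830 at an unadjusted p under 0.05, and with only these 4 libraries in the fit also 0, with 803, while DESeq2 called 66 on all 14 libraries. In the simulation of this comparison 51.6% of the calls of DESeq2 were false. Without AP_CD9High replicate 1 or replicate 2, 2 genes were called. Cd9 lost its call without any one of the 4 libraries, at log2 fold changes of 1.53 to 1.88 (adjusted p from 0.157 to 0.569), and in 12 of 18 alternatives (range 0.000842 to 0.569). Rac1 lost it in 3 of 18 (adjusted p = 0.0505 without AP_CD9Low replicate 2, range 3.44e-23 to 0.208), Cilp in 10 of 18 (range 4.29e-05 to 0.549) and Pcdhgc4 in 7 of 18 (range 0.00281 to 1). With legacy = TRUE 2 genes were called.

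CD29 cells differed from the AP cells by contractile and mural transcripts. Acta2 was at 1396 ± 146.6 CPM in CD29 (n = 2) against 97.72 ± 32.28 CPM in AP (n = 4), a log2 fold change of 3.89 (SE 0.21, adjusted p = 1.74e-08). Tagln, which encodes an actin-binding smooth muscle protein, was at 132.1 ± 11.7 against 4.885 ± 2.708 CPM (4.86, SE 0.31). The pericyte gene Rgs5 was at 104.9 ± 4.192 against 0.7937 ± 0.8229 CPM (7.41, SE 0.46, and 6.9 without AP_CD9Low replicate 1, which was at 0, with no exact fold without AP_CD9Low replicate 2). The adhesion molecule gene Bcam was at 14.39 ± 5.285 CPM against 0 counts in AP, at least 483-fold higher. Progenitor markers were lower, with Dpp4 at -3.29 (SE 0.33, adjusted p = 1.18e-05), Cd34 at -3.19 (SE 0.31) and Ly6a at -2.65 (SE 0.39). Itgb1, which encodes CD29, was at 762.5 ± 163.9 against 623.6 ± 42.98 CPM and was not called (0.29, SE 0.19, adjusted p = 0.59). Of 808 genes called, 464 were higher and 344 lower.

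Contractile genes rose in 16 of 26 cases (list adjusted p = 1.95e-24; 20 adjusted over the list alone) and pericyte and smooth muscle markers in 10 of 16, with 1 lower (adjusted p = 1.5e-10; 11 and 1 adjusted over the list alone). Fibroblast progenitor markers fell in 13 of 27 and rose in 3 (adjusted p = 6.14e-13; 18 lower and 5 higher adjusted over the list alone), with dermatopontin (Dpt) at -2.14 (SE 0.21). Adipocyte identity genes passed as a list (adjusted p = 1.47e-05) with 2 of 26 called higher and 1 lower (5 and 1 adjusted over the list alone). The higher ones were the lipid-binding genes Fabp4 (2.78, SE 0.36) and Cd36 (1.55, SE 0.26), which endothelial cells and macrophages also express. The mean log2 CPM of the adipocyte list was 1.14 in CD29 replicate 1 and 0 in CD29 replicate 2, against -1.17 to -0.43 in the AP libraries. Adipoq had 227 counts and Plin1 57 in CD29 replicate 1, and both had 0 in CD29 replicate 2. These 4 lists were called with an estimated correlation as well. Chemokines and cytokines were lower in 12 of 31 and higher in 5 (adjusted p = 6.95e-07, and adjusted p = 0.13 with an estimated correlation; 16 lower and 8 higher adjusted over the list alone). Il6 was at -2.53 (SE 0.27) and Saa3 at -3.19 (SE 0.33). Matrix genes were lower in 11 of 34 and higher in 6 (adjusted p = 0.000703, and adjusted p = 0.316 with an estimated correlation; 18 lower and 8 higher adjusted over the list alone). Col14a1 was at -2.89 (SE 0.3) and Tnc at 2.0 (SE 0.2). The protease gene Mmp3 was at -2.86 (SE 0.26) and the signalling genes Wnt5a at 3.29 (SE 0.32) and Inhba at 2.37 (SE 0.23).

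Markers of other cell types were also higher in CD29. Macrophage and monocyte markers were higher in 16 of 26 cases (adjusted p = 2.62e-19, and adjusted p = 0.0636 with an estimated correlation; 22 adjusted over the list alone). C1qa was at 262.7 ± 5.762 against 97.23 ± 41.05 CPM. Endothelial markers were higher in 8 of 21 (adjusted p = 7.9e-07, and adjusted p = 0.0636 with an estimated correlation; 12 higher and 1 lower adjusted over the list alone). Esam was at 26.09 ± 2.983 against 4.429 ± 2.285 CPM. The count of 808 fell to 342 without CD29 replicate 1, 340 without CD29 replicate 2 and 509 without AP_CD9High replicate 2. Of 31 genes followed through the alternatives, 4 lost the call without CD29 replicate 1 and 4 without CD29 replicate 2. Cd36 was among the latter (adjusted p = 0.0522, log2 fold change 1.33, range 7.05e-05 to 0.0522 over its alternatives). The count was 383 with legacy = TRUE and 452 against a fold of 1.5, and with library size alone as the scaling 864 genes were higher and 260 lower.

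DN cells had more of the markers of erythrocytes and macrophages than the AP cells. The beta globin gene Hbb-bs was at 3292 ± 315.0 CPM in DN (n = 2) against 31.5 ± 14.59 CPM in AP (n = 4), a log2 fold change of 6.76 (SE 0.35, adjusted p = 3.11e-09). The mast cell tryptase gene Tpsb2 was at 109.3 ± 40.5 CPM in DN, at 0 in both AP_CD9Low libraries and at 0.69 and 2.22 CPM in AP_CD9High (adjusted p = 4.62e-07), so no exact fold is given. The myeloid receptor gene Cd14 was at 1456 ± 380.7 against 275.0 ± 85.32 CPM (2.46, SE 0.21) and the keratin gene Krt15 at 26.05 ± 11.94 CPM against 0 counts, at least 876-fold higher. Dpp4 (-2.16, SE 0.3, adjusted p = 0.000217), Cd34 (-2.24, SE 0.29) and Ly6a (-2.04, SE 0.37) were lower and Cd9 was higher (1.28, SE 0.22), whereas Itgb1 (-0.1, SE 0.19, adjusted p = 0.947) was not called. Of 1242 genes called, 841 were higher and 401 lower.

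Macrophage and monocyte markers rose in 23 of 26 cases (list adjusted p = 6.31e-38; 23 adjusted over the list alone) and erythrocyte markers in 5 of 6 (adjusted p = 4.3e-16; 6 adjusted over the list alone). Pericyte and smooth muscle markers rose in 5 of 16 with 3 lower (adjusted p = 9.26e-05; 8 higher and 3 lower adjusted over the list alone). These 3 lists were called with an estimated correlation as well. Keratinocyte markers were higher in 16 of 24, and in 20 adjusted over the list alone. Their list had adjusted p = 3.83e-19, and adjusted p = 0.0519 with an estimated correlation. Their counts came to 0.014% of the TMM-scaled library size of DN replicate 1 and 0.204% of that of DN replicate 2. Endothelial markers were higher in 9 of 21 (adjusted p = 7.98e-07, and adjusted p = 0.0519 with an estimated correlation; 11 adjusted over the list alone). Lymphocyte and mast cell markers were higher in 6 of 18 (adjusted p = 3.83e-06, and adjusted p = 0.0633 with an estimated correlation; 7 adjusted over the list alone), and neutrophil markers in 6 of 13 (adjusted p = 2.28e-05, and adjusted p = 0.0794 with an estimated correlation; 7 adjusted over the list alone). Progenitor markers were lower in 14 of 27 and higher in 3 (adjusted p = 3.08e-09, and adjusted p = 0.0519 with an estimated correlation; 18 lower and 3 higher adjusted over the list alone). Matrix genes were lower in 13 of 34 and higher in 3 (adjusted p = 7.98e-07, and adjusted p = 0.163 with an estimated correlation; 16 lower and 3 higher adjusted over the list alone). Tenascin X (Tnxb) was at -3.36 (SE 0.41). Chemokines and cytokines went both ways, 9 higher and 10 lower of 31 (adjusted p = 0.194; 10 higher and 12 lower adjusted over the list alone), with Tnf at 2.84 (SE 0.28) and Il1a at 2.57 (SE 0.24). Contractile genes were higher in 8 of 26 and lower in 1 (adjusted p = 1.7e-05, and adjusted p = 0.0519 with an estimated correlation; 10 higher and 1 lower adjusted over the list alone). Acta2 was at 2.23 (SE 0.21).

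Skeletal muscle genes were called higher in 6 of 17 cases (adjusted p = 1.26e-06, and adjusted p = 0.179 with an estimated correlation; 12 adjusted over the list alone), but the rise lay in DN replicate 1. The mean log2 CPM of the list was 2.08 there, -1.87 in DN replicate 2 and -2.79 to -2.08 in the AP libraries. For Acta1, at 93.0 CPM in DN replicate 1 and 3.4 CPM in DN replicate 2, the call ended without DN replicate 1 (log2 fold change 1.66, adjusted p = 0.708). Ly6a lost its call in 2 of 20 alternatives, among them the fit without DN replicate 2 (log2 fold change -1.7), with a range of -2.49 to -1.56. Cd9 lost its call in 1 of 20 (range 1.19 to 1.53). The alpha globin gene Hba-a2 has a near-identical copy in Hba-a1, so its 0 counts in all AP libraries are uncertain. The count of 1242 fell to 670 without DN replicate 1 and 724 without DN replicate 2, and to 620 with legacy = TRUE. With library size alone as the scaling, 1154 genes were higher and 266 lower.

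Between CD29 and DN, 11 genes were called, 2 higher in CD29 and 9 lower, against 1455 at an unadjusted p under 0.05 in edgeR. Acta2 was at 1396 ± 146.6 against 441.3 ± 43.31 CPM (log2 fold change 1.66, SE 0.25, adjusted p = 0.0143, n = 2 per group). The myosin light chain gene Myl9 was at 210.8 ± 29.99 against 52.96 ± 4.984 CPM (1.99, SE 0.34, adjusted p = 0.0345). Hbb-bs (-4.63, SE 0.42), Hbb-bt (-4.62, SE 0.49), Hba-a1 (-4.53, SE 0.44), the erythroid heme synthesis gene Alas2 (-4.97, SE 0.45) and Hba-a2 were lower. The remaining 4 were chosen after their values were seen: the mast cell protease genes Tpsb2 (-2.63, SE 0.46) and Cma1 (-3.28, SE 0.51), and mt-Cytb (-1.52, SE 0.26) and mt-Nd6 (-1.91, SE 0.29) of the mitochondrial genome. Itgb1, the gene of the protein that the column headers tie to this sort, was at 762.5 ± 163.9 against 583.5 ± 7.685 CPM and was not called (0.39, SE 0.22, adjusted p = 0.715).

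All 26 contractile genes had a positive log2 fold change (median 0.85, list adjusted p = 1.06e-16; 2 called, 16 adjusted over the list alone), as had all 16 pericyte and smooth muscle markers (median 1.54, adjusted p = 2.01e-06; 0 called, 7 adjusted over the list alone). Erythrocyte markers fell in 5 of 6 (adjusted p = 3.69e-19; 5 adjusted over the list alone), and these 3 lists passed with an estimated correlation as well. Macrophage and monocyte markers were negative in all but 1 of 26 cases (median -1.09, adjusted p = 1.31e-17, and adjusted p = 0.109 with an estimated correlation), with 0 called and 20 lower adjusted over the list alone. Keratinocyte markers had 0 of 24 positive values, with 9 lower adjusted over the list alone (median -2.63, list adjusted p = 2.39e-12, and adjusted p = 0.112 with an estimated correlation). Their mean log2 CPM was -0.41 and 1.14 in the CD29 libraries, 1.36 in DN replicate 1 and 4.17 in DN replicate 2. As a share of the TMM-scaled library size the groups overlapped, at 0.005% and 0.024% in CD29 against 0.014% and 0.204% in DN. Acta2, Myl9, Tpsb2, Cma1, mt-Cytb and mt-Nd6 each lost the call without CD29 replicate 1 and without CD29 replicate 2, in fits that called 5 genes, and Acta2 and Myl9 also without either DN library (adjusted p for Acta2 of 0.0878, 0.196, 0.101 and 0.14). The count was 2 with legacy = TRUE, 51 with the reanalysed set alone and 109 in DESeq2. With library size alone as the scaling it was 5 higher and 12 lower.

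AdipoqTraced and AP cells come from different sets, so the differences between them cannot be told apart from differences between the sets. Adipoq was at 0 counts in all 4 AP libraries, at least 313-fold lower than in AdipoqTraced. Without AdipoqTraced replicate 1 the bound was at least 90.1-fold and Adipoq was not called (adjusted p = 0.0762, range 0.00118 to 0.0762 over its alternatives). Col12a1 was at 3667 ± 104.0 CPM (n = 2) against 351.6 ± 69.41 CPM (n = 4), a log2 fold change of 3.39 (SE 0.17, adjusted p = 9.87e-10). Acta2 was at 545.0 ± 84.92 against 97.72 ± 32.28 CPM (2.53, SE 0.21) and Rgs5 at 142.0 ± 46.17 against 0.7937 ± 0.8229 CPM (7.85, SE 0.45, and 7.34 without AP_CD9Low replicate 1). Dpp4 (-2.18, SE 0.31), Cd34 (-2.87, SE 0.3), Ly6a (-2.98, SE 0.4) and Cd9 (-1.5, SE 0.26) were lower, and Pdgfra (0.07, SE 0.36) and Itgb1 (-0.15, SE 0.2) were not called. In all, 6812 of 18394 genes were called, 4032 higher and 2780 lower.

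Contractile genes were higher in 20 of 26 cases and lower in 3 (list adjusted p = 1.26e-05, and adjusted p = 0.112 with an estimated correlation; 20 and 3 adjusted over the list alone). Pericyte and smooth muscle markers moved with them, higher in 10 of 16 and lower in 1 (adjusted p = 0.00498, and adjusted p = 0.112 with an estimated correlation; 10 and 1 adjusted over the list alone). Nonmuscle myosin Myh9 was at 2.82 (SE 0.19). Glycolysis and hypoxia genes were lower in 15 of 25 and higher in 3 (adjusted p = 7.32e-07, and adjusted p = 0.112 with an estimated correlation; 17 lower and 3 higher adjusted over the list alone). The triosephosphate isomerase gene Tpi1 was at -3.52 (SE 0.25). Adipocyte identity genes were higher in 10 of 26 and lower in 1 (adjusted p = 0.00963, and adjusted p = 0.178 with an estimated correlation; 10 and 1 adjusted over the list alone). The lipid droplet gene Plin1 was at 7.885 ± 4.332 CPM against 0 counts, at least 276-fold higher, and at least 169-fold without AdipoqTraced replicate 1. Keratinocyte markers were higher in 18 of 24 (adjusted p = 2.95e-08, and adjusted p = 0.208 with an estimated correlation; 19 adjusted over the list alone). Krt1 was at 90.22 ± 64.22 CPM against 0 counts. Genes of the immediate early and dissociation response were lower in 16 of 27 and higher in 5 (adjusted p = 0.00018, and adjusted p = 0.208 with an estimated correlation; 16 and 5 adjusted over the list alone). Ier2 was at -3.96 (SE 0.29) and Fosb at 3.31 (SE 0.2). Of the 27 lists, 13 were called with the preset correlation and 0 with an estimated one, while the directional test of fry called 16.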

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

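Mitochondrial genome genes left out, legacy = TRUE and lists within one set were chosen after the data were seen; the other alternatives were planned. With 2 libraries per group, a fit without 1 library leaves a lone sample that is assumed to vary like the other groups. Adipocyte libraries held 2952186 and 3255546 counts outside the mitochondrial genome, so a count of 0 there sets a less strict bound. No fit at matched depth was run. No identifier came from assembled transcripts, so leaving such identifiers out was not run. Genes followed through the alternatives stayed on their side of the threshold, with no called gene changing direction, in 700 of 719 values in AdipoqTraced against Adipocyte, 468 of 593 in AdipoqTraced against CD26, 346 of 358 in CD26 against Adipocyte, 130 of 162 in AP_CD9High against AP_CD9Low, 605 of 620 in CD29 against AP, 548 of 559 in DN against AP, 192 of 249 in CD29 against DN and 436 of 437 in AdipoqTraced against AP. Among called genes, Atp5b alone reversed, to 0.69 with library size alone in AdipoqTraced against Adipocyte. Genes not called changed sign in some alternatives: Dpp4 (-0.19 to 2.43) in AdipoqTraced against Adipocyte, Cd9 (-0.33 to 0.26) and Ly6a (-0.55 to 0.1) in AdipoqTraced against CD26, Itgb1 (-0.17 to 0.16) in DN against AP, Pdgfra and Itgb1 in AP_CD9High against AP_CD9Low, and Pdgfra and Itgb1 in AdipoqTraced against AP. Library size alone does not correct for the share of the mitochondrial genome; otherwise the cause was not tested.

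With library size alone, 8195 genes were called in AdipoqTraced against Adipocyte, 1166 in AdipoqTraced against CD26, 6501 in CD26 against Adipocyte and 17 in CD29 against DN, which also had 17 with relative log expression. Without a filter, AdipoqTraced against CD26 had 422, and without robust AP_CD9High against AP_CD9Low had 2. Against a fold of 1.5, a stricter question by construction, counts were 202 in AdipoqTraced against CD26, 2 in AP_CD9High against AP_CD9Low, 452 in CD29 against AP and 6 in CD29 against DN. With legacy = TRUE they were 342, 2, 383 and 2 in the same comparisons and 620 in DN against AP. DESeq2 called 3402 in AdipoqTraced against Adipocyte, 1251 in AdipoqTraced against CD26, 3288 in CD26 against Adipocyte, 66 in AP_CD9High against AP_CD9Low and 109 in CD29 against DN. With only the groups compared, fewer libraries by construction, counts were 1145 in AdipoqTraced against Adipocyte, 92 in AdipoqTraced against CD26, 32 in CD29 against DN and 0 in AP_CD9High against AP_CD9Low in edgeR (803 at an unadjusted p under 0.05, 66 in DESeq2 on all 14 libraries). With 1 set only, the spread of each gene also came from that set. The counts were then 75 in AdipoqTraced against CD26, 2 in AP_CD9High against AP_CD9Low and 51 in CD29 against DN.

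Without 1 library, the count of genes ran from 960 to 1986 in AdipoqTraced against Adipocyte, 69 to 878 in AdipoqTraced against CD26, 964 to 1404 in CD26 against Adipocyte and 340 to 612 in CD29 against AP. It ran from 670 to 985 in DN against AP, 5 to 15 in CD29 against DN, 5155 to 5992 in AdipoqTraced against AP and 0 to 5 in AP_CD9High against AP_CD9Low in edgeR (830 at an unadjusted p under 0.05 where it was 0, 66 in DESeq2 on all 14 libraries). Lists called ran from 2 to 5 in AP_CD9High against AP_CD9Low. With an estimated correlation, lists called were 10 in AdipoqTraced against Adipocyte, 12 in CD26 against Adipocyte, 4 in CD29 against AP, 3 in DN against AP, 3 in CD29 against DN and 0 in AdipoqTraced against CD26, in AP_CD9High against AP_CD9Low and in AdipoqTraced against AP. The fry test called 0 in AP_CD9High against AP_CD9Low and 4 in CD29 against DN. The cause was not tested.

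No shared effect of the replicate number was seen: deviations of same-numbered libraries correlated at -0.05 to 0.08 within the sets (7809 genes). This cannot exclude a shared animal or day. It also matched DN replicate 2, with label number 3, to libraries of replicate 2 with label number 4. With a replicate block, AP_CD9High against AP_CD9Low had 1 gene called, and no other count moved by over 1.5 times. Adipoq in AdipoqTraced against CD26 was then called (5.04, SE 1.07, adjusted p = 0.0418, range 0.0418 to 0.581 over its 18 alternatives). With the label number as replicate block, counts were 290 in AdipoqTraced against CD26, 422 in DN against AP, 5 in CD29 against DN, 4252 in AdipoqTraced against AP and 0 in AP_CD9High against AP_CD9Low in edgeR (634 at an unadjusted p under 0.05, 66 in DESeq2 on all 14 libraries). The block uses residual degrees of freedom by construction.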

Other observations

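The tests on carry-over of adipocyte and of skeletal muscle RNA were chosen after the results were seen. Rac1, which encodes a GTPase that drives cell protrusion, was low in AdipoqTraced (65.82 and 70.27 CPM) and in AP_CD9Low (103.27 and 122.0 CPM). It stood at 579.94 and 620.75 CPM in CD26 and 377.72 and 405.02 CPM in AP_CD9High. Gbp2b, an interferon-induced GTPase gene, was at 8.82 to 104.74 CPM in every library of the new set and at 0 in all 8 of the reanalysed set. Adipoq was at 6.7 CPM in CD29 replicate 1 and 1.75 CPM in DN replicate 1, and at 0 in the other library of each group.

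Keratinocyte markers differed between the DN libraries, with a mean log2 CPM of 1.36 in replicate 1 and 4.17 in replicate 2. Skeletal muscle markers went the other way, at 2.08 and -1.87.

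The difference between AdipoqTraced and AP could reflect how the sets were prepared, since no group is in both. The log2 fold change correlated with GC content (Spearman rho -0.25 across 18364 genes), which met the prediction for a GC bias. The margin was small, since AdipoqTraced against CD26, within one set, gave 0.22. Gene length gave 0.1, between the bounds set, so it cannot tell. Of 5 genes present throughout one set and absent from the other, none lay within 1 Mb of another, and a share of 1.0 of draws did as well. The median draw also held 0, so the test could not have told the cases apart, a reading made after the value was seen.

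Adipocyte transcripts in AdipoqTraced could be carried over from adipocytes, which would leave all identity genes at a similar share of the Adipocyte level. A first test decides nothing: in AdipoqTraced replicate 2, 4 of 11 genes (36.4%) lay within 3-fold of the median share of 0.13%, but CD26 levels of genes such as Lpl (275.18 CPM) would hide so small a share, and in replicate 1 the median was 0. A second took the share that Adipoq needs and left out genes whose CD26 level exceeds it. In replicate 1 Adipoq needs 1.76%, and 2 of 18 other genes (11.1%) lay within 3-fold. Plin4 had 0 counts where 214.6 were needed, Acvr1c 0 of 78.7 and Car3 594 of 3341.7, whereas Trarg1 would need 15.58%. At the share that Adipoq needs, most of these genes fell short in replicate 1, with 15 below the 3-fold range and 1 above. The test rests on 1 anchor gene in 1 library, and amplified reads are not independent molecules. It therefore cannot exclude carry-over as the only source in replicate 1, which stays open. In replicate 2 Adipoq needs 0.27%, and 5 of 7 genes (71.4%) lay within 3-fold, with Trarg1 above at 3.03%, so carry-over stays open there.

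Skeletal muscle transcripts in Adipocyte could come from muscle RNA or cells in the sort. Of 17 genes, 15 (88.2%) were higher in both Adipocyte libraries than in the other 4 of the set. This restates the lower levels already seen in AdipoqTraced and CD26, so it decides nothing and the source stays open. Acta1 was at 43.0 and 113.3 CPM and Ttn at 191.2 and 358.0 CPM in Adipocyte.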
